A study of Mus musculus with 20 samples.

How the data were processed

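Bulk poly(A) RNA-seq was made from cortex, hippocampus and cerebellum of mice expressing APOBEC1-YTH or APOBEC1-YTHmut after tamoxifen, with 900 ng of total RNA per library and a directional library kit, per the labels' protocols. Reads were aligned with STAR 2.7.5 and the build mm10, per the submitters' processing notes. Sites were called with APOBEC1-YTHmut libraries as background for C-to-U edits, per the series design in the labels. The site caller, its thresholds, its depth minimum and the way the libraries of a region were combined are not given in the sources used here. For each region the authors deposited 1 list without a header, whose 6 columns hold the chromosome, start, end, gene symbol, a value and the strand. The deposited value is a fraction between 0 and 1 that was read as the share of edited reads at the site in the APOBEC1-YTH libraries of the region combined, an assumption that the lists leave open; it is printed here as percent and called the editing level. No value was below 1%, no position was repeated within a list, and positions are given 1-based.

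The lists hold no depth, no value per library and no APOBEC1-YTHmut value. Depth per library is therefore unknown, no spread between animals could be computed, and p-values and intervals describe these pooled lists and cover neither animals nor read counting. The 20 libraries came from 4 APOBEC1-YTH and 3 APOBEC1-YTHmut animal numbers in the labels. Each of the 4 APOBEC1-YTH animal numbers had a library from every region. Because levels were pooled and without depth, differences at shared sites were described without a test per site.

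A site was shared between regions when chromosome, position and strand were identical, and a gene was methylated in a region when at least 1 site was listed with its symbol. Symbols were matched to the GRCm38.p6 RefSeq gene table, the assembly of mm10, for 3691 of 3731 genes (3677 by symbol and 14 by synonym), and used for gene spans and the distance to the 3′ end. Transcript parts and sequence context were not analysed here, because no exon annotation or genome sequence was used. Shares have exact binomial 95% intervals, and medians and SDs of log2 ratios have bootstrap intervals from 1000 draws of genes.

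Gene lists were tested in 3 ways. The two-sided Fisher's exact test compared membership in each of 25 lists with methylation in a region, over genes with a site in any region, for 75 tests. The level test compared the median difference in level over a list's shared sites with 10000 random gene sets of the same number, for lists with at least 3 such genes. The site-number test compared the mean log2 ratio of site numbers, with a pseudocount of 1, with 10000 random gene sets matched on total sites. All families were adjusted by Benjamini-Hochberg with a threshold of 0.05. The tests were checked on simulated data. The Fisher test recovered 5 of 20 planted lists of 15 genes put wholly into cerebellum, among 3731 genes. The site-number test recovered 5 of 10 lists with added sites, among 3731 genes. Both would thus miss many real differences of these sizes. For the level test, log2 ratios were shuffled over sites, and 3 of 10 lists shifted by 0.5 on that scale were recovered, among 1636 genes. The reported level test uses differences in percentage points, and shuffling removes any likeness of sites within a gene. Its power and its false calls are therefore not known from this simulation. In lists with nothing planted, the Fisher test made 1 call in 1440 tests, the level simulation 0 in 240 and the site-number test 3 in 240.

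Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, per region, the 8 genes with the most sites, the 8 with the highest-level site and the 8 with the most sites and none in the other regions. It also named, per pair of regions, the 6 largest rises and 6 largest falls at shared sites, 1 site a gene, and up to 4 members of a list, those with the most sites first; predicted genes were replaced by the next gene. Some genes that the rule names are not reported here. Chosen after the data had been seen were the limit of 35% and every result without sites above it, the ranking of genes with 5 or more shared sites, the site-number test and its alternatives, the log2 ratio and the minimum of 3 genes in the level test, and a list of choroid plexus markers. A test of whether 1 scale factor explains the differences between lists was dropped, since scaling cannot change the SD of log2 ratios, and so, after its result had been seen, was one on the neighbours of sites at 35% or more, since their isolation is part of the pattern to be explained. Alternatives were a level of at least 10%, merging of sites within 10 nt, sharing within 10 or 50 nt, at least 2 sites for a methylated gene, scaling to the same median and 1 value a gene. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.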

Results

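The data describe N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, in the mouse brain. The mice carried a transgene induced by tamoxifen that encodes APOBEC1-YTH, a fusion of the cytidine deaminase APOBEC1 with the m6A-binding YTH domain, so that cytidines near an m6A are read as uridines in the sequenced RNA. APOBEC1-YTHmut, named in the labels as the background control for such edits, was measured in the same regions. The 20 bulk RNA-seq libraries comprised 4 APOBEC1-YTH libraries each from cortex, hippocampus and cerebellum, and 3, 2 and 3 APOBEC1-YTHmut libraries from these regions in that order. The APOBEC1-YTH libraries of all regions came from the same 4 animal numbers. Mice received 20 mg/kg tamoxifen every 24 h for 5 days, and tissue was taken 7 days after the last dose. Each region was represented by 1 list of edited sites, read as marking nearby m6A, with 1 editing level per site, so the levels have no replicate error and the read depth behind them is unknown. The interval given with a share is an exact 95% binomial interval that treats sites or genes as independent and does not cover differences between animals.

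The first question was how many edited sites were listed in each region and in which transcripts. A site is an edited cytidine and is not shown to be a separate m6A. Another listed site lay within 50 nt of 57.6% of sites with a highest level of 1 to 5%. Depth is unknown, and hippocampus had 2 background libraries against 3 in the other regions, so the numbers do not rank the regions by m6A. Cortex held 17878 sites in 3163 genes, hippocampus 13461 sites in 2547 genes and cerebellum 11391 sites in 2228 genes. In cortex the genes with the most sites were Apc, a component of the Wnt pathway destruction complex, with 98 sites, the long noncoding RNA gene Oip5os1 with 80, Paqr8 with 69, the RNA-binding protein gene Celf4 with 65, the protein kinase C gene Prkce with 63, the myosin gene Myo5a with 61, the BDNF receptor gene Ntrk2 with 61 and the sodium channel gene Scn1a with 59. Hippocampus was led by Oip5os1 with 70 sites, Celf4 with 63, Ids with 61, Prkce with 59, Paqr8 with 58, the astrocytic glutamate transporter gene Slc1a2 with 57, the microtubule-associated protein gene Map1b with 55 and the transcription factor gene Zbtb18 with 53. Cerebellum was led by Map1b with 72 sites, Paqr8 with 69, Slc1a2 with 62, Frrs1l with 61, Scn1a with 59, and Hapln4, the calcium pump gene Atp2b2 and the G-protein signalling regulator gene Rgs8 with 57 each.

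Site numbers of single genes differed in size between the lists. Apc had 98 sites in cortex, 26 in hippocampus and 4 in cerebellum, and all 4 of the cerebellar sites were listed in every region. Zbtb18 had 57, 53 and 8 sites in these regions, and Prkce had 63, 59 and 12. Rgs8 had 1 site in cortex, 1 in hippocampus and 57 in cerebellum. Paqr8 had 69, 58 and 69 sites, of which 47 were at the same nucleotide in all 3 regions. Sites were concentrated in few genes: 526 genes with 10 or more sites held 58.5% of the cortical sites, while 1065 cortical genes, 33.7%, had 1 site. Protein-coding genes accounted for 3653 of the 3691 genes matched to the reference annotation and long noncoding RNA genes for 36. The median site lay 1518.5 nt upstream of the annotated 3′ end of its gene, measured along the genome, and 87.0% of sites within a gene span lay within 5 kb of it.

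Editing levels were low at most sites. The median level was 2.91% in cortex, 2.82% in hippocampus and 3.36% in cerebellum, and no listed site was below 1%. Levels of 10% or more were reached by 1170 cortical sites (6.54%), 826 hippocampal sites (6.14%) and 1024 cerebellar sites (8.99%). The highest cortical levels were at Tm7sf3 (69.7%; chromosome 6, position 146623613, mm10), Uggt2 (65.0%; chromosome 14, 119026527), Kmt2a, which encodes a histone H3K4 methyltransferase (64.7%; chromosome 9, 44819875), Vwa8 (63.3%), Fam32a (63.3%), Rhobtb2 (61.0%), Fjx1 (60.5%) and A2ml1 (59.4%). Hippocampus was highest at Fam32a (71.5%; chromosome 8, 72222815), Ift46 (66.7%), Agrn (63.6%), Ttyh2 (61.9%), Uggt2 (60.5%; chromosome 14, 118998130), Mboat7 (60%), Tm7sf3 (59.5%) and Hmgcs1, which encodes a cholesterol synthesis enzyme (59.2%). Cerebellum was highest at Iars2 (94.3%; chromosome 1, 185289443), Cadm3 (78.0%), Stoml1 (72.5%), Mapkbp1 (70.0%), Eps8 (69.1%), Prelid3b (62.5%), Kbtbd2 (62.2%) and Gipc1 (62.0%).

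These highest sites belonged to a separate group in the distribution of levels. The number of sites fell to 35 at a highest level of 30 to 35% and rose again to 70 at 50 to 55%, and 284 sites in 242 genes reached 35% in at least 1 region. Another listed site lay within 50 nt of 13.0% of these 284 sites (9.34 to 17.5%), against 70.4% (68.2 to 72.6%) of the 1714 sites with a highest level of 10 to 35%. The limit of 35% was set after the distribution had been seen, and results are given below with and without the group where it leads them. Among sites under 35% in every list, high levels in cortex were at Dgkq (33.3%) and Ddn, which encodes the dendritic protein dendrin (33.1%). In hippocampus the highest were at Ivd (34.8%), Ncdn (32.8%) and Arl5a (32.6%), and in cerebellum at Ccnl2 (34.9%), the vacuolar ATPase gene Atp6v1c1 (34.8%) and Dnajb4 (34.2%).

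**Figure D1:**
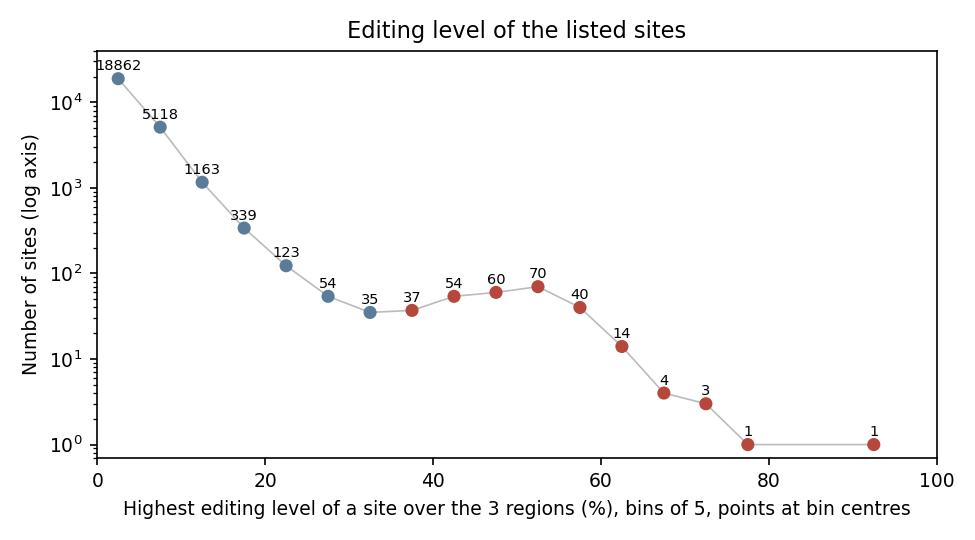
Number of sites (log axis) against the highest editing level of a site over the 3 regions in bins of 5 percentage points, each point at the centre of its bin; red points mark bins from 35% upward. Counts fall from 18862 sites below 5% to 35 sites at 30 to 35% and rise to 70 sites at 50 to 55%.

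The next question was how far the regions shared sites. Of the 25978 sites in any list, 4942 (19.0%) were listed at the same nucleotide in cortex, hippocampus and cerebellum. Cortex and hippocampus shared 9379 sites, which were 69.7% (68.9 to 70.5%) of the hippocampal sites. Cortex and cerebellum shared 6627 sites, 58.2% (57.3 to 59.1%) of the cerebellar sites, and hippocampus and cerebellum shared 5688, 49.9% (49.0 to 50.9%) of the cerebellar sites. With levels below 10% removed from every list, these 3 shares were 67.9%, 39.4% and 32.5%. A shared site then had to reach 10% in both regions. Listing at any level rose with the level instead. Cortex listed 94.1% of hippocampal sites at 10 to 20%, against 49.8% of those at 1 to 2%. For cerebellar sites these shares were 72.1% and 45.1% in cortex, and 63.5% and 40.3% in hippocampus. Hippocampus listed 58.2% of cortical sites at 35% or more, against 78.2% of those at 20 to 35%. This share also fell for cortical sites in cerebellum (63.7% against 68.1%) and cerebellar sites in hippocampus (62.1% against 67.5%). It rose for hippocampal sites in cortex and in cerebellum and for cerebellar sites in cortex. Lists of one region alone held 6814 sites for cortex, 3336 for hippocampus and 4018 for cerebellum. Sites listed in cortex alone had a median level of 2.46% against 4% for cortical sites found in both other regions, and in cerebellum these medians were 2.88% and 3.99%. The positions that could have been called in each region are not known, so no p-value was computed, and a site absent from a list is not shown to be unmethylated.

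Methylated genes, those with at least 1 listed site, were shared more widely than sites. Of 3731 genes, 1608 (43.1%) were methylated in all 3 regions, and 89.0% (87.8 to 90.2%) of hippocampal genes and 83.3% (81.6 to 84.8%) of cerebellar genes were also methylated in cortex, and 75.9% (74.1 to 77.7%) of cerebellar genes in hippocampus. With levels below 10% removed from every list, these 3 shares were 80.4%, 57.1% and 48.0%. A shared gene then needed a site at 10% or more in both regions. Cerebellum alone listed 289 genes, among them the potassium channel subunit gene Kcng4 with 47 sites at a mean level of 9.49%, Strip2 with 36 sites at 7.59%, Car8 with 30 sites at 3.69%, the calcium pump gene Atp2a3 with 23 sites at 8.27%, the phospholipase gene Plcb4 with 21 sites at 3.27% and Sgpp2 with 15 sites at 5.52%. Hippocampus alone listed 195 genes, led by Fibcd1 with 20 sites at a mean of 5.20% and Nr3c2, which encodes the mineralocorticoid receptor, with 6 sites at 4.01%; Tgfb2, Hars and Zbtb20 had 4 sites each, Kctd4 and Eif4b 3 and Orc5 2. Cortex alone listed 648 genes, among them the synaptic organiser gene Cbln2 with 19 sites at a mean of 5.34%. Others were Fam131b with 10 sites, Kcnh7, Kcnh1, Ipcef1 and Pik3r1 with 9 each, and Pde4b with 8.

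**Figure D2:**
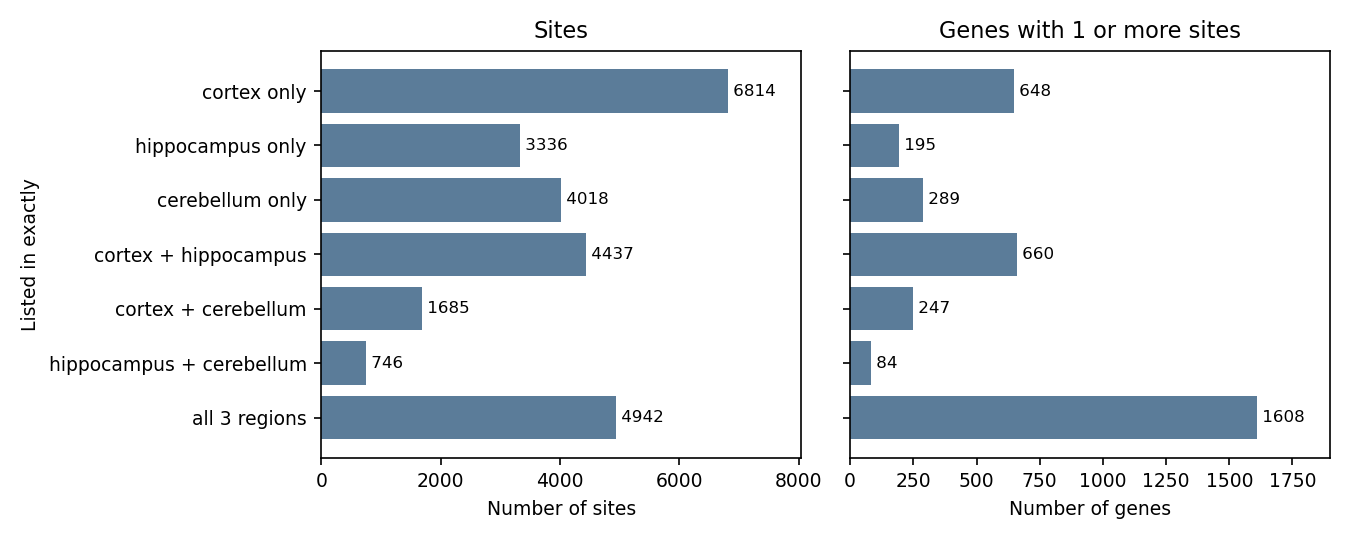
Number of sites (left) and of genes with 1 or more sites (right) listed in exactly the regions named on the vertical axis. All 3 regions share 4942 of the sites and 1608 of the genes, and cortex alone holds 6814 sites and 648 genes.

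Editing levels at shared sites were then compared between the regions. For cortex and cerebellum, the genes given are those with the largest median log2 ratios in either direction. The 14 shared sites of Atrnl1, which encodes attractin-like 1, averaged 3.70% in cortex and 13.5% in cerebellum, and 13 of them were higher in cerebellum. The neurofilament gene Nefh was higher there at 8 of 8 sites (4.45% and 11.1%), Nsg1 at 8 of 8 (3.19% and 10.8%), Elmod1 at 6 of 6 (2.64% and 9.66%), Vstm2a at 5 of 5 (4.88% and 11.4%), Kcnab2 at 7 of 8 (3.61% and 9.50%), Insyn1 at 11 of 12 (2.40% and 6.07%) and the GABA-B receptor gene Gabbr2 at 12 of 13 (2.28% and 5.20%). In the other direction, Celf4 was lower in cerebellum at 25 of its 27 shared sites, with means of 7.98% in cortex and 2.96% in cerebellum. The insulin-like growth factor binding protein gene Igfbp5 (12.5% and 3.004%), the potassium channel gene Kcnd2 (7.18% and 2.63%) and Kifc2 (8.59% and 2.59%) were lower at 8 of 8 sites, Kcnc1 at 7 of 7 (6.95% and 2.58%), the adenylyl cyclase gene Adcy1 at 5 of 5 (10.4% and 2.71%), Zbtb18 at 7 of 8 and the calcineurin gene Ppp3ca at 10 of 11. This ranking by the median log2 ratio over genes with 5 or more shared sites was chosen after the data had been seen. It selects genes whose sites lie mostly on 1 side, so these counts do not show how common that is.

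**Figure D3:**
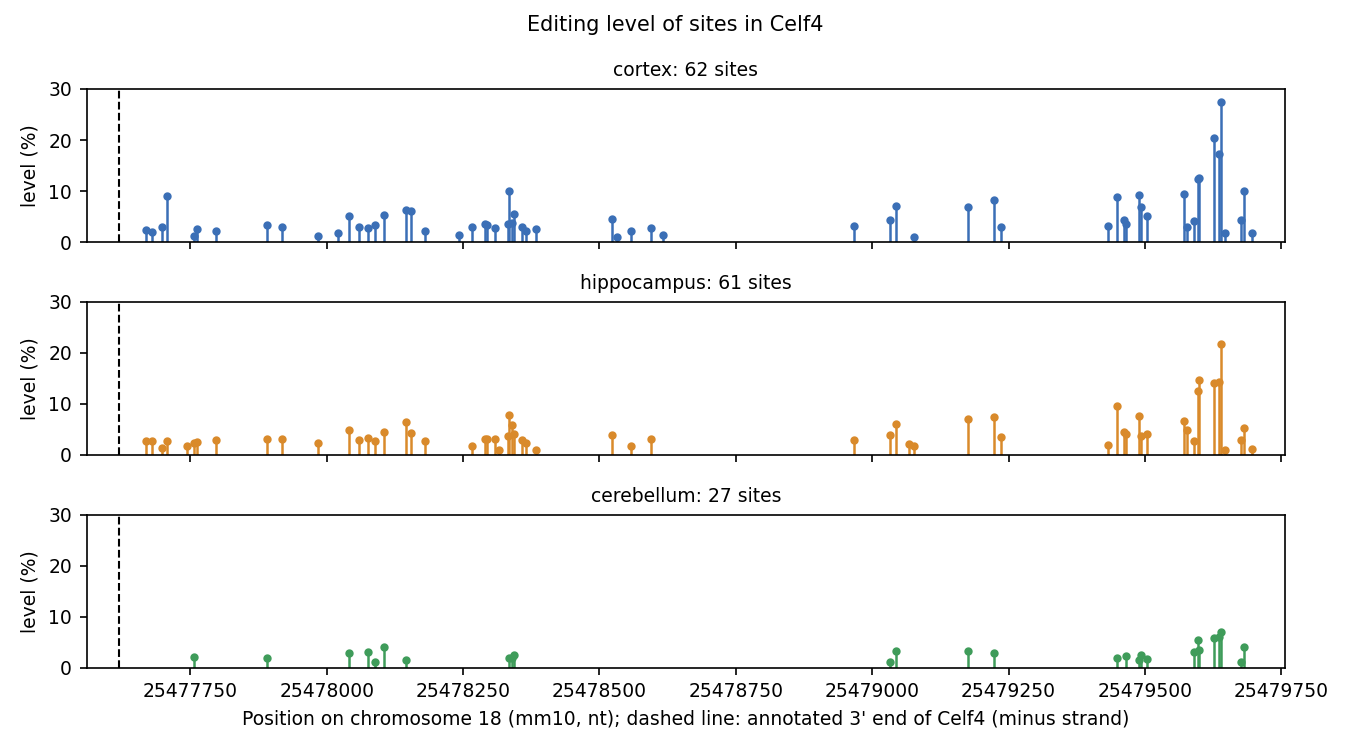
Editing level (%) of the listed sites of Celf4 within 5 kb of its annotated 3′ end, against position on chromosome 18 (mm10), with 1 panel per region and the gene end as a dashed line. Cortex has 62 sites, hippocampus 61 and cerebellum 27, and the highest site, at position 25479639, was at 27.4%, 21.8% and 6.95% in these regions.

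Across all shared sites the levels of the regions were centred near each other. A site not listed in 1 region of a pair does not enter these ratios, so both levels are at least 1%. The median log2 ratio of hippocampus to cortex was -0.02 (-0.04 to 0.00, bootstrap 95% interval over genes), that of cerebellum to cortex 0.06 (0.01 to 0.10) and that of cerebellum to hippocampus 0.04 (-0.01 to 0.08). The spread was wider with cerebellum: the SD of the log2 ratio was 0.71 for hippocampus and cortex, 0.94 for cerebellum and cortex and 0.92 for cerebellum and hippocampus. Levels lay within 2-fold of each other at 84.5% of the sites shared by cortex and hippocampus, at 72.9% for cortex and cerebellum and at 73.5% for hippocampus and cerebellum. Spearman correlations across sites, which are not independent replicates, were 0.71, 0.55 and 0.57. With 1 value per region and no depth, no single site could be tested. The shares of sites higher in the second-named region were 48.4%, 52.6% and 51.9%, and 48.8%, 54.7% and 56.2% with 1 value a gene. Scaling to the same median gave 50.2%, 49.3% and 48.9%. By its construction it pulls such shares towards 50%, so it cannot decide whether there is a direction. No direction is drawn from the shares, since the levels are pooled values without depth or spread between animals.

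**Figure D4:**
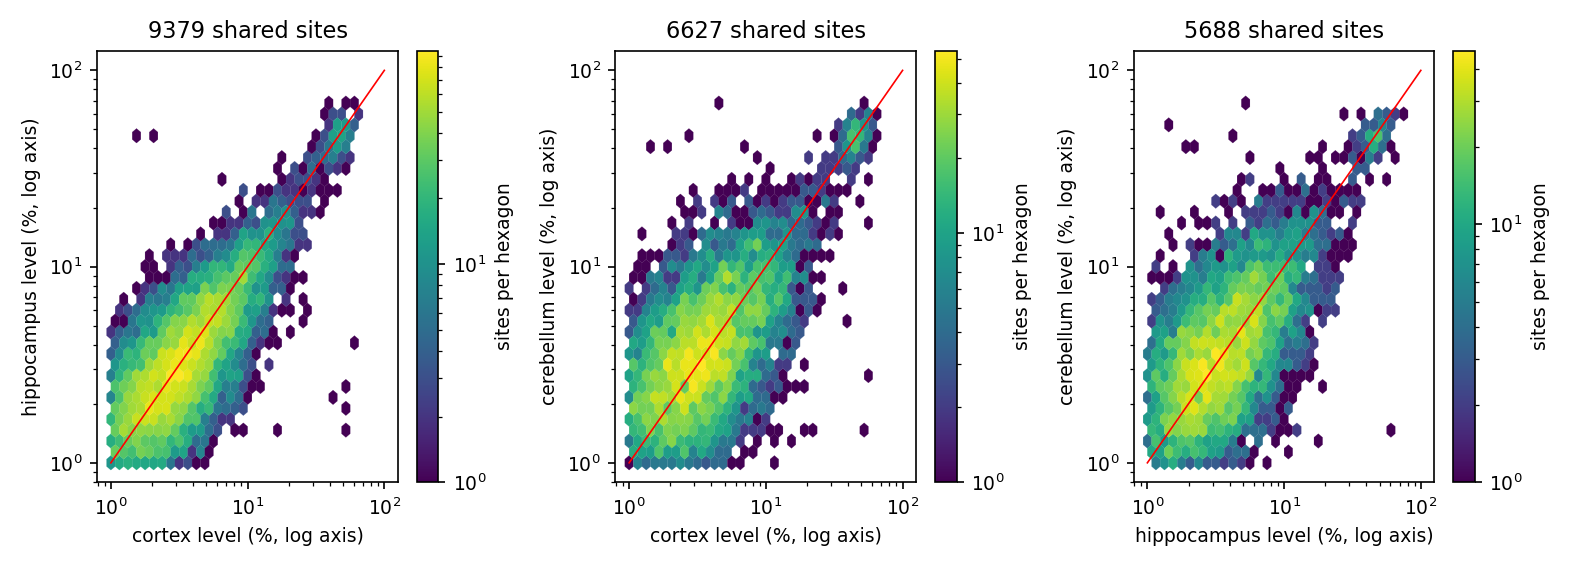
Editing levels (%, log axes) of sites listed in both regions of a pair, as numbers of sites per hexagon (colour, log scale), with equality as a red line. The 9379 sites of cortex and hippocampus lie closer to the line (SD of the log2 ratio 0.71) than the 6627 of cortex and cerebellum (0.94) and the 5688 of hippocampus and cerebellum (0.92).

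The largest differences at single sites came mostly from the group at 35% or more. The sites whose hippocampal level lay most above the cortical one were in Trappc4 (1.92% to 45.5%), the guanine deaminase gene Gda (1.62% to 44.2%) and Ift46 (40% to 66.7%), followed by Ttyh2, Aqp11 and Mboat7. Those most below it were in Kmt2a (64.7% to 4%), Zc3h11a (53.8% to 1.52%), the nuclear envelope gene Sun2 (53.1% to 2.53%), Zfyve9 (50% to 2%) and Bace1, which encodes beta-secretase (41.2% to 2.13%), followed by Ttc5. The sites whose cerebellar level lay most above the cortical one were in Stoml1 (4.55% to 72.5%), Ctso (2.7% to 45.5%), Shisa4 (1.46% to 43.2%), Trappc4 (1.92% to 40.9%), Atrnl1 (7.27% to 42.1%) and the arginine methyltransferase gene Prmt8 (8.97% to 35.9%). Those most below it were in Sun2 (53.1% to 2.86%), Hmgcs1 (50.4% to 1.49%), the synaptotagmin gene Syt2 (57.1% to 17.9%), Spon1 (36.8% to 5.36%), Vsnl1 (56.3% to 26.5%) and Fgf1 (50% to 20.8%). Between hippocampus and cerebellum, Stoml1 (5.13% to 72.5%), Zc3h11a (1.52% to 52.4%), Kmt2a (4% to 44.8%), Zfyve9, Bace1 and Prmt8 were most above in cerebellum, and Hmgcs1 (59.2% to 1.49%), Vsnl1 (54.8% to 26.5%), Agrn (63.6% to 37.5%), Tspyl4, Cdk5r1 and App most below.

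Without that group, other sites led the differences between cortex and cerebellum. Most above in cerebellum were Ptpn4 (5.77% to 27.9%), Prmt8 (10.2% to 31.7%), Nsg1 (3.16% to 24.6%), Odr4 (2.30% to 22.7%), Elmod1 (7.00% to 26.4%) and Arhgap32 (4.39% to 23.5%). Most below were Celf4 (27.4% to 6.95%), the calcium-dependent kinase gene Camkk2 (20.7% to 1.49%), Tspyl4 (30.1% to 11.5%), Igfbp5 (20.3% to 2.42%), the clock output factor gene Tef (19.1% to 1.35%) and App, which encodes the amyloid precursor protein (23.3% to 5.71%). From cortex to hippocampus, Aqp11 (6.25% to 28.6%), Ntrk2 (8.93% to 24.6%), Scn1a (10% to 23.9%) and the GABA-A receptor gene Gabra5 (9.68% to 23.1%) were among the sites most above in hippocampus. Col25a1 (27.3% to 5.36%), Slitrk1 (25.5% to 5.77%), Meis2 (25% to 7.27%) and the long noncoding RNA gene Tug1 (22.03% to 4.71%) were among those most below.

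Gene groups were compared next, with 25 fixed lists of synaptic, signalling, housekeeping and cell type marker genes. Of all genes with a site in any region, 84.8% were methylated in cortex, 68.3% in hippocampus and 59.7% in cerebellum. A list's numbers falling in this order are thus not by themselves particular to the list. All 13 Purkinje cell markers with any site were methylated in cerebellum, against 8 in cortex and 5 in hippocampus. Calb1, which encodes calbindin, had 45 cerebellar sites, 1 cortical and 0 hippocampal ones, the nuclear receptor gene Rora had 37, 5 and 0 in that order, Car8 had 30, 0 and 0, and Itpr1, which encodes the inositol trisphosphate receptor, had 16, 4 and 3. Of the 10 immediate early genes with any site, 9 were methylated in cortex, 6 in hippocampus and 1 in cerebellum. Egr3 had 18 cortical and 10 hippocampal sites, Nr4a2 7 and 10, and Jun, with 5, 4 and 3, was the only one of them listed in cerebellum. Neither list passed Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over 75 tests, adjusted p = 0.0660 for both), nor did any other: 0 of 75 tests passed adjustment at 0.05 and 14 had an unadjusted p below 0.05. With 2 or more sites required of a methylated gene, 3 of Fisher's exact tests passed. Purkinje cell markers were methylated more often than all genes in cerebellum (12 of 12, against 58.3% of all genes with such sites in any region; Fisher's exact test, adjusted p = 0.0497) and less often in cortex (4 of 12, against 85.6%; adjusted p = 0.00383). Hippocampal markers were also methylated less often in cortex (2 of 7, against 85.6%; Fisher's exact test, adjusted p = 0.0374). Marker genes are chosen by where they are expressed, and expression was not measured here. These calls are therefore not told apart from differences in expression.

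Of 23 postsynaptic scaffold genes, 21 were methylated in cortex, 20 in hippocampus and 13 in cerebellum, with Camk2a, which encodes the alpha subunit of calcium/calmodulin-dependent kinase II, at 25, 26 and 25 sites and Shank1 at 23, 29 and 19. Of the 22 scaffold genes with any site, these were 95.5%, 90.9% and 59.1%, against 84.8%, 68.3% and 59.7% of all genes with any site. Of 29 synaptic vesicle release genes 24 were methylated in cortex, 21 in hippocampus and 19 in cerebellum, with the neurexin gene Nrxn3 at 50, 33 and 26 sites. Of 30 voltage-gated channel genes 24, 23 and 17 were methylated in the same order; Scn1a had 59, 27 and 59 sites and the potassium channel gene Kcnq3 had 35, 18 and 0. Among 15 GABA receptor genes 11, 11 and 7 were methylated, with Gabra3 at 41, 20 and 0 sites, and among 25 glutamate receptor genes 13, 10 and 7, with Gria1 at 26, 31 and 38 sites and Grm5 at 22, 26 and 0. Axon guidance and adhesion genes reached 13, 15 and 8 of 34 and pan-neuronal markers 14, 14 and 11 of 16, with the neurofilament gene Nefl at 16, 19 and 29 sites.

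Of 17 astrocyte markers 13 were methylated in cortex, 14 in hippocampus and 13 in cerebellum; Slc1a2 had 53, 57 and 62 sites and the water channel gene Aqp4 18, 16 and 40. Of 17 oligodendrocyte markers 6, 6 and 5 were methylated, with Mobp, which encodes a myelin protein, at 21, 22 and 16 sites, and of 10 oligodendrocyte precursor markers 2, 1 and 2, with the phosphatase gene Ptprz1 at 43, 33 and 35. Of 15 microglia markers 1 was methylated in cortex (P2ry12), 0 in hippocampus and 1 in cerebellum (Lgmn), and endothelial and mural markers reached 4 of 15 in each region, with Rgs5 at 21, 12 and 10 sites. Interneuron markers reached 9, 6 and 6 of 14, with the vesicular GABA transporter gene Slc32a1 at 5, 2 and 11 sites. Markers of excitatory cortical and hippocampal neurons reached 10, 7 and 2 of 15. Among them Camk2a had the most sites, with 25, 26 and 25, and the glutamate transporter gene Slc17a7 had 7, 9 and 1. Cerebellar granule cell markers reached 4 of 17 in each region.

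Among the other lists, few cytoplasmic ribosomal protein genes were methylated: 2 of 42 genes in cortex, 1 in hippocampus and 0 in cerebellum. Nuclear-encoded oxidative phosphorylation genes reached 5, 5 and 4 of 29, with Sdha at 8, 9 and 6 sites. Chromatin regulators reached 14, 13 and 6 of 35, ubiquitin ligases 16, 14 and 13 of 23, with Trim2 at 21, 25 and 14 sites, and genes of mTOR, PI3K and MAPK signalling 15, 10 and 11 of 26. Wnt and Notch signalling genes reached 6, 4 and 3 of 22, and m6A writers, readers and erasers 6, 6 and 4 of 21, with the reader gene Ythdf2 at 13, 15 and 8 sites. Of the Ythdf2 sites 12, 15 and 8 lay in a single stretch of 478 nt, where reads of the APOBEC1-YTH transgene, which carries a YTH domain, were not told apart from reads of the gene.

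**Figure D5:**
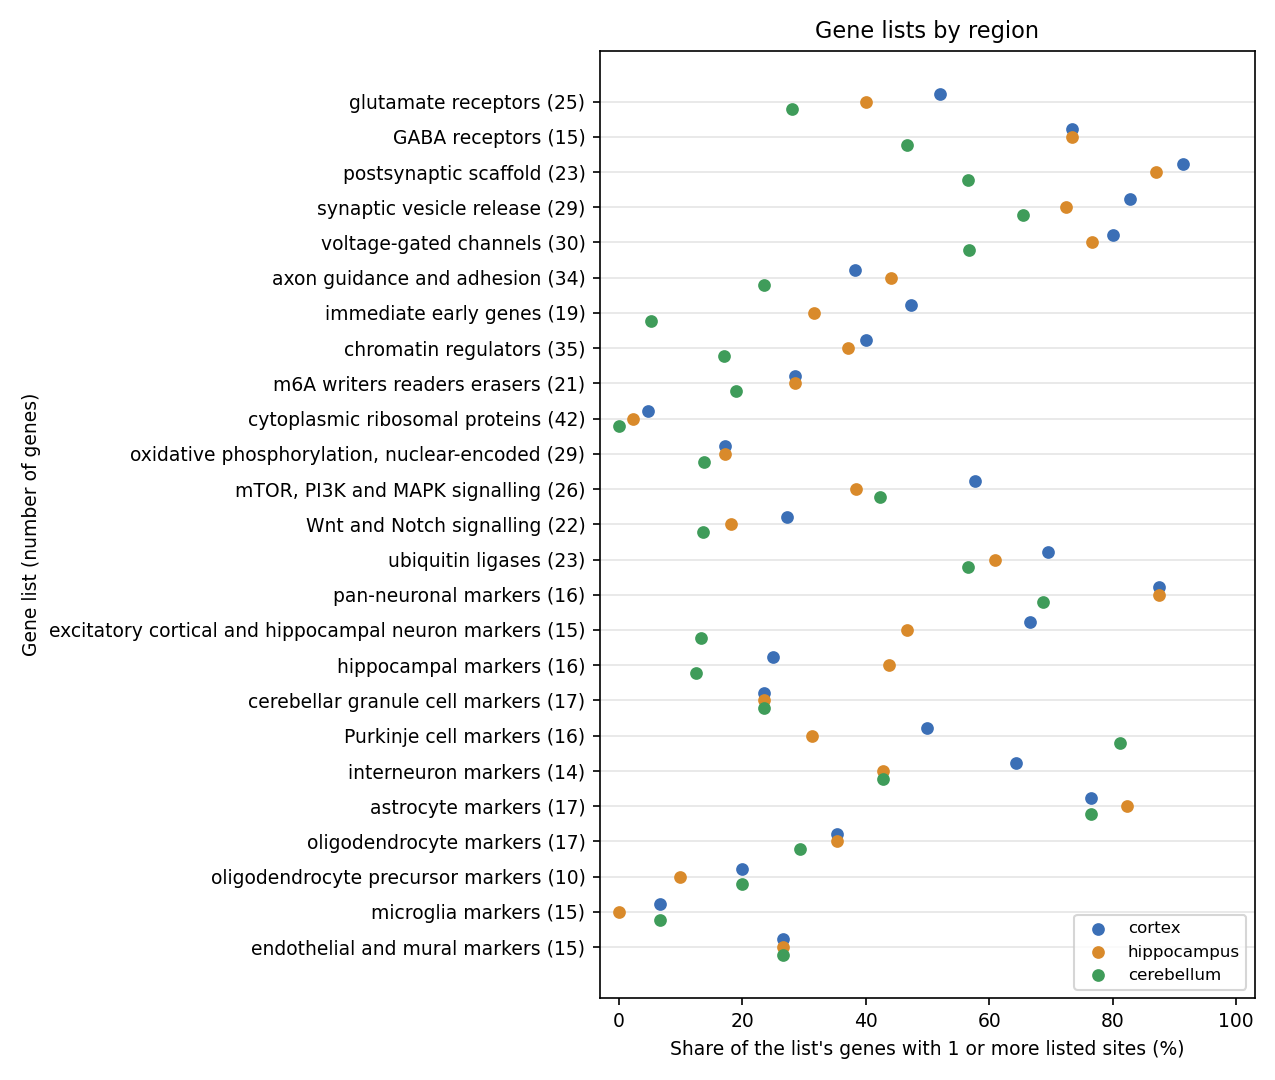
Share of each list's genes (%) with 1 or more listed sites, by region, with the number of genes in the list in parentheses. Among Purkinje cell markers 13 genes have sites in cerebellum, against 8 in cortex and 5 in hippocampus, and among immediate early genes 1 has sites in cerebellum, against 9 and 6.

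The number of sites per gene was then compared list by list, a test chosen only after the planned Fisher test had called no list. Expression, without which no site of a gene can be listed, was not measured here. Marker lists are chosen by where genes are expressed. Differences in site number below are therefore not told apart from differences in expression or depth, and do not show a difference in m6A. Purkinje cell markers held 216 sites in cerebellum against 19 in cortex and 9 in hippocampus, with mean log2 ratios of 2.61 and 3.05. Hippocampal markers held 54 sites in hippocampus against 22 in cortex (mean log2 ratio 1.28), with Fibcd1 at 20 and 0 sites, Nr3c2 at 6 and 0, Wfs1 at 10 and 9 and Lmo3 at 11 and 11. Immediate early genes held 3 sites in cerebellum against 42 in cortex and 28 in hippocampus, with mean log2 ratios of -1.86 and -1.80. In a permutation test against 10000 random gene sets matched on total sites, 5 of 66 comparisons passed adjustment (Benjamini-Hochberg): adjusted p = 0.00440 for hippocampal markers and for both Purkinje comparisons, each from an unadjusted p of 0.0002, the smallest these sets can give, and 0.0396 and 0.0422 for immediate early genes. In the same permutation test, the calls on immediate early genes were lost without the gene with the most sites (adjusted p = 0.115 against cortex and 0.183 against hippocampus), the second also when sites within 10 nt were merged (0.0713), with mean log2 ratios of -1.56, -1.47 and -1.63 in that order; Calb1 stands in both the Purkinje and the hippocampal list.

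Editing levels of the lists were compared at shared sites. Among chromatin regulators, the median difference from hippocampus to cerebellum was 17.5 percentage points over the 3 shared sites, which lay in Kmt2a (4% and 44.8%), Kmt2e (30% and 47.5%) and Chd4 (54.1% and 52.8%). All 3 of these sites belong to the group at 35% or more. The 74 sites of GABA receptor genes shared by cortex and hippocampus had a median difference of 0.685 points, with 43 of them higher in hippocampus. The 17 shared sites of hippocampal markers in this pair, in 3 genes, went the other way, with a median difference of -1.97 points and 13 of them lower in hippocampus. The 120 sites of synaptic vesicle release genes shared by cortex and cerebellum had a median difference of -0.715 points, with 81 lower in cerebellum. In the permutation test against 10000 random gene sets, 1 of 55 comparisons passed adjustment (Benjamini-Hochberg), that of chromatin regulators (adjusted p = 0.0110); GABA receptors and hippocampal markers (adjusted p = 0.438 for both) and synaptic vesicle release (adjusted p = 0.674) did not. Without sites at 35% or more the chromatin regulators had no shared site left to test, and their call was lost when the permutation test used the log2 ratio in place of the difference (adjusted p = 0.728), where hippocampal markers had the smallest p of all lists but did not pass either (adjusted p = 0.132).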

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

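Alternatives with sites under 35%, the log2 ratio, and those of the site-number test were chosen after the data had been seen. No paired analysis was possible because the lists hold 1 combined value per region and none per animal. Depth minima, leaving out replicates, and results on APOBEC1-YTHmut, transcript parts and sequence context were not run, since the lists give no depth or library values and no exon annotation or genome was used; what depth limits can therefore not be stated. With levels of at least 10% only, cortex kept 1170 sites in 730 genes, hippocampus 826 in 546 and cerebellum 1024 in 606, by construction fewer. The share of these sites also at 10% or more in cortex was 67.9% for hippocampus and 39.4% for cerebellum, and 32.5% of those in cerebellum were at 10% or more in hippocampus. For genes with a site at 10% or more in both regions, these shares were 80.4%, 57.1% and 48.0%. Sites listed below 10% in the other region do not count in these shares. Sharing within 10 nt gave 73.4%, 61.8% and 53.6% for sites, and within 50 nt 82.0%, 70.0% and 62.6%, as a wider window must. With 2 or more sites per gene, 91.2% of hippocampal genes were also methylated in cortex. Scaling to the same median moved the share of sites higher in the second region across 50%, to 50.2% for cortex and hippocampus, 49.3% for cortex and cerebellum and 48.9% for hippocampus and cerebellum, as this scaling pulls the share towards 50% by construction; 1 value a gene gave 54.7% and 56.2% for the last 2 pairs. The Fisher test passed 3 times with 2 or more sites per gene and 0 times with levels of at least 10% or under 35%, as with all sites. The level test called 0 under 35% and 0 with the log2 ratio, against 1, and also 1 with scaling, 1 value a gene or lists of 1 or more genes. Beyond these by-construction shifts, the cause was not tested. Merging sites within 10 nt, or keeping those under 35%, left every number of sites, and the latter of genes, within 1.5 times its value, and every share stayed within its interval under 35%. The site-number test called 4 with merged sites, 6 without the top gene of each list and 5 under 35%, against 5. Without the top gene, both calls on immediate early genes were lost and 3 were gained in the permutation test: excitatory neuron markers had fewer sites in cerebellum than in cortex (mean log2 ratio -1.81, adjusted p = 0.0158) and hippocampus (-1.65, adjusted p = 0.0242), and so had hippocampal markers against hippocampus (-2.59, adjusted p = 0.00330, from -1.58 with Calb1). The top gene of the excitatory list is Camk2a, with 25, 26 and 25 sites in cortex, hippocampus and cerebellum. With it the 2 excitatory ratios were -1.63 and -1.42, and neither passed the permutation test (adjusted p = 0.0836 and 0.147).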

Other observations

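Noncoding RNA and the m6A machinery added further examples, chosen after their values were seen. The 36 long noncoding RNA genes held 368 sites, of which Oip5os1 alone had 95 over the 3 regions, 41 of them listed in every region. In Ythdf2, which encodes an m6A reader with a YTH domain, 15 of 16 sites lay within 478 nt on chromosome 4 (positions 132204180 to 132204657, mm10), 19264 to 19741 nt upstream of the annotated 3′ end, and the highest of them was at 6.17%. This stretch held 12 sites in cortex, 15 in hippocampus and 8 in cerebellum. The transgene carries a YTH domain whose sequence was not used here, so it was not tested whether these sites lie in reads of the transgene and not of Ythdf2 itself, and they are not shown to be methylation of Ythdf2. Of 15 choroid plexus markers, a list written after Ttr had been seen, 3 had sites: Ttr, which encodes transthyretin, had 8 sites in cerebellum and 0 in the other regions, Enpp2 had 2 in cortex, 1 in hippocampus and 11 in cerebellum, and Kl had 1, in cerebellum.

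Of the tests below, those on the distance to the gene end, on genes without sites in other regions and on the correlation within genes were set before their results were seen, and the others after. No biological explanation of these patterns was tested beyond the regions themselves, and differences between the tissues stay open.

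The first pattern is the separate group of 284 sites at 35% or more. Most of them were isolated, but 37 had another listed site within 50 nt. Sampling noise at poorly covered sites is argued against by recurrence: 138 of 237 such cortical sites (58.2%) were listed in hippocampus, and 117 were at 35% or more there, which is 84.8% (77.7 to 90.3%) of those listed and 49.4% (42.8 to 55.9%) of all 237. Both regions came from the same APOBEC1-YTH animals, so recurrence between animals is not shown. Methylation of the same kind as elsewhere, only higher, was predicted to lie at a like distance to the gene end. The prediction failed, with a median of 3016 nt (2292 to 3815), against 1731 nt (1595 to 1932) at 10 to 35%. This median also rose with level below 35%, from 1454 nt at 1 to 5% to 1865 nt at 20 to 35%. Unlike genes were compared too, since 27.8% of sites in the group were the only one of their gene, against 4.26% at 10 to 35%. The distance alone therefore does not decide against this explanation. The genes of the group were crowded into fewer stretches of 10 Mb than random genes with sites (permutation p = 0.0001, the smallest 10000 draws can give), with 4.09% of all sites on chromosome 14 in the group against 0.137% on chromosome 11, so a strain or animal variant against the reference, absent from the background animals, is a candidate explanation. As the cause of every site in the group, a variant carried by all the animals is argued against by the 10 sites, among them Hmgcs1 and Stoml1, that were below 10% in cortex or cerebellum, 6.02% (2.93 to 10.8%) of the 166 listed in both and at 35% or more in either, where 1% was set as the bound, and by 7 of 151 such sites for cortex and hippocampus and 7 of 119 for hippocampus and cerebellum. All 3 lists came from the same 4 APOBEC1-YTH animal numbers, so a variant in some of them would also be present in every region. How the animals were combined is unknown, so their shares in each list may differ. Of the 7 for cortex and hippocampus, Trappc4, Kmt2a, Bace1 and Zc3h11a lie in the 10 stretches with the most sites of the group. Gda, Sun2 and Zfyve9 do not. Sites not listed in a region have no level there and leave the question open, among them Iars2, listed at 94.3% in cerebellum alone, 86 of 237 cortical sites not listed in cerebellum, 21 of these in genes with other sites there, and 99 not listed in hippocampus, 37 of these in such genes.

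The second pattern is that 38.1% of cortical sites were listed in cortex alone. A gene without any site in the other regions accounted for 15.2% (14.4 to 16.1%) of these 6814 sites, so absence of the whole transcript does not account for most of them. Levels near the detection threshold may account for many: in genes methylated in all 3 regions, 43.0% of cortical sites at 1 to 2% were listed in cortex alone, against 7.99% (6.09 to 10.2%) of those at 10 to 35%. That remainder lay above the 5% set as the bound for the threshold as the whole cause. Depth, which is unknown here, stays open.

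The third pattern is the wider spread of levels between cortex and cerebellum. Independent noise at each site is argued against by the correlation within genes: log2 ratios of sites 200 nt or more apart in the same gene had an intraclass correlation of 0.276 over 2572 sites in 753 genes, against 0.0283 at the 95th percentile and 0.0571 at the highest of 1000 random reassignments. For hippocampus and cerebellum it was 0.252 over 2162 sites in 650 genes, against 0.0341 at the 95th percentile and 0.0768 at the highest. For cortex and hippocampus it was 0.0445, against 0.0248 at the 95th percentile and 0.0635 at the highest. A shift per gene is thus consistent with the 0.276, and it may be biological, or technical where expression, depth or the editor's activity differs by gene or cell type between regions. None of these could be tested with 1 pooled value per region.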
